A study of Arabidopsis thaliana with 8 samples.

How the data were processed

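Transcript levels were measured in inflorescence tissue of Arabidopsis thaliana, flower stages 9 to 12, on Affymetrix ATH1 arrays. Each of 4 genotypes had 2 biological replicates, and each array received 6 ug of total RNA from pooled tissue (n = 3 per the labels). The genotypes were Col-0 (wild type), ddm1-2, rdr6-15 and the double mutant ddm1-2 rdr6-15. The deposited values are log2 signals per probe set. Per the labels, the authors summarised them with RMA, whose version and settings are not given in the sources used here. Between arrays the quartiles differed slightly, and no scaling was added.

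Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. Genes came from the annotation of the platform, which listed 14016 probe sets, 13513 of them with one symbol and 503 with several genes. No gene was listed for 8794 probe sets. Locus tags and biotypes were taken from the TAIR10.1 reference table, by name only. A single locus was found for 13436 tested probe sets, of which 12443 were protein coding, 989 pseudogenes or transcribed pseudogenes and 4 other noncoding. Genomic positions were not analysed here, since no build is named for the arrays.

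A linear model with a mean per genotype was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistics, 4 residual degrees of freedom, prior degrees of freedom 2.82). Comparisons were ddm1-2 with Col-0, rdr6-15 with Col-0, the double with each of the other genotypes, the interaction, and the effects of each mutation averaged over the other. P-values were two-sided and adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. The number of replicates and the spread between them both limit the precision. Data were simulated with the spread pooled over all 8 arrays, rdr6-15 included, and not with that of the Col-0 and ddm1-2 arrays alone. On these data the comparison of ddm1-2 with Col-0 recovered 6 of 50 probe sets changed by 1 log2 unit. It recovered 38 of 50 changed by 2 and 47 of 50 changed by 4, with 12 false calls.

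The level without signal was taken, after the data were seen, from 27 control probe sets for Bacillus transcripts, and the highest of their means over the arrays was used as the limit. Genes to name were fixed by rule. Per comparison these were the called transposon probe sets, and up to 8 others highest and lowest by log2 difference among those with one gene, an adjusted p under 0.05 and no overlap between the arrays compared. Where fewer than 3 passed, the 3 with the smallest p were added as values that did not pass. Lists of genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry. Of 20 lists fixed by locus, 5 had 3 or more probe sets and were tested. Classes among called probe sets were compared by Fisher's exact test, two-sided. It treats probe sets as independent, which those shared by related sequences are not, so its p-values may be too small.

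The comparisons, tests, thresholds, naming rule, 20 lists and most alternatives were chosen before the data were examined. Those alternatives were a replicate block, fitting only the genotypes compared, quantile normalization, median centring, leaving out dim or shared probe sets, a trended and robust variance, a difference of at least 2-fold, an adjusted p under 0.01 and leaving out each array in turn. Transposon probe sets were to be found by transposon wording in the annotation. That wording matched 0 tested probe sets, so 4 probe sets of 12 transposon loci listed by name were used, as planned for that case. All 12 loci have the biotype pseudogene.

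Chosen after the data were seen were the class of annotated pseudogenes (989 probe sets, which also holds ordinary pseudogenes), the lists of late pollen genes (12 probe sets), plastid-encoded genes (69) and nuclear photosystem genes (5), array weights, the protein-coding genes named as risers beyond the rule, and the counts without rdr6-15 replicate 1 given beside those of all arrays. The late pollen list was written from general knowledge and leaves out loci already seen to change. These lists and the 84 pseudogene probe sets called higher in the averaged ddm1-2 effect form one family of 5 for adjustment, apart from the lists fixed beforehand. Adjusting the 84 probe sets as a family of their own was also tried after the results were seen. It was not kept, and for the double against ddm1-2 it equals the unadjusted p printed beside the adjusted one.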

Results

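Signal was measured for 22746 probe sets on 8 arrays, 2 for each of 4 genotypes: Col-0, ddm1-2, rdr6-15 and the double mutant. DDM1 is a chromatin remodeller that keeps transposons silent, and RDR6 is an RNA-dependent RNA polymerase that makes the precursors of secondary small interfering RNAs. The series concerns such RNAs arising from transposons. Median log2 signal per array lay between 3.73 and 3.82. The level without signal was read from 27 control probe sets for Bacillus transcripts, which plants lack. Their means were 2.27 to 2.76, except for 1 at 3.56, and a mean at or below 3.56 is called control level here. Differences against control level are lower limits, and their order carries no meaning. Correlation between arrays across probe sets was at least 0.944 among 7 arrays, while rdr6-15 replicate 1 correlated at 0.852 to 0.879 with the others. Across probe sets, which are not independent replicates, these correlations describe the arrays only.

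The comparison of ddm1-2 with Col-0 asks which transcripts change when DDM1 is lost with RDR6 present. AT2G13160, an annotated pseudogene, rose by at least 9.03 log2 units (SE 0.26, adjusted p = 2.26e-05), from control level (2.80) to a mean of 11.83. The annotated pseudogenes AT2G10640, AT2G12300 and AT2G12240 rose by at least 8.65, 8.62 and 8.10. AT1G33130, AT2G12980 and AT2G13870, of the same class, rose by at least 7.61, 7.60 and 7.52. The probe sets of all these pseudogenes are of the types _s_at or _x_at, which related sequences share. Their signal cannot be assigned to single loci, and the rises may not be separate. The protein-coding locus AT1G58025 rose by at least 7.98 (SE 0.16, adjusted p = 9.84e-06). Protein-coding risers picked out after their values were seen were AT1G59930 with 5.83 and, each from control level, AT1G36240 with at least 6.20, AT5G26270 with 6.10, AT2G15560 with 5.47 and AT4G29200 with 3.81. Among the 4 probe sets of transposons listed by name, AT2G23480 (VANDAL21, a DNA transposon of the Mutator type) rose by at least 1.78 (adjusted p = 0.00953). Its probe set is shared too. AtMu1 (AT4G08680) differed by 1.91 with an adjusted p of 0.118 over all probe sets, and CAC1 (AT2G12210) and AT2G23500, both at control level in every genotype, by -0.29 and 0.33, with 2 of the 4 called when adjusted over the list alone. The named transposons as a list were higher by camera (median 1.06, adjusted p = 0.0106), with an adjusted p = 0.222 with an estimated correlation. In the double the same list did not pass by camera, against Col-0 (median 0.39, adjusted p = 0.0774, and 0.425 with an estimated correlation) or against rdr6-15 (median 0.37, adjusted p = 0.0731, and 0.415 with an estimated correlation). By fry, which tests whether the set moves one way and compares it with no other genes, it passed against both (adjusted p = 0.0113 and 0.0176). QQS, the 1 gene of 10 on the list of genes silenced by methylation that the annotation matched to a probe set, rose by 3.34 (adjusted p = 0.00128).

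In all, 92 probe sets were higher and 39 lower in ddm1-2 than in Col-0. Of the 92, 79 were at control level in Col-0, and of the 39, 20 were at control level in ddm1-2. Annotated pseudogenes, a class defined after the data were seen, made up 71 of the 92 higher and 0 of the 39 lower (Fisher's exact test for the higher, odds ratio 79.9, p = 2.15e-78), with 2076 probe sets of any kind and direction at an unadjusted p under 0.05 in limma. Of these 71, 18 had probe sets of their own and 53 had probe sets of the types _s_at or _x_at, which related sequences share; with all such probe sets left out 13 pseudogenes were called higher. Leaving out 1 array moved the total from 131 to between 31, without Col-0 replicate 1, and 1084, without either rdr6-15 array. Without rdr6-15 replicate 1 the counts were 489 higher, 135 of them annotated pseudogenes, and 595 lower.

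**Figure D1:**
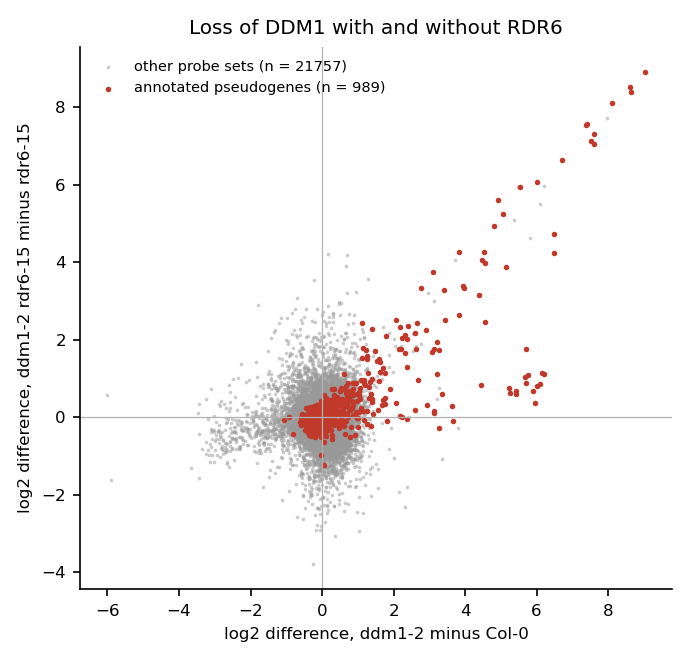
Log2 difference of ddm1-2 minus Col-0 (horizontal) against the double minus rdr6-15 (vertical) for each of 22746 probe sets, with 989 annotated pseudogenes in red. Pseudogenes with large differences lie to the upper right, and a group of them is high on the horizontal axis alone.

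Genes with lower signal in ddm1-2 included AT5G39520, which fell by 3.45 (adjusted p = 0.0337), and AT1G05340, which fell by 3.25 (adjusted p = 0.00397). AT3G56600, AT2G25625 and AT3G61930 fell too, with differences of -2.42, -2.14 and -1.83. AT1G09500, AT5G51030 and AT1G18990 fell to control level, so that their differences of -3.11, -1.77 and -1.77 are limits. The lower calls did not hold when an array of either genotype was left out: 0 of any gene were left without Col-0 replicate 1, ddm1-2 replicate 1 or ddm1-2 replicate 2, and 1, AT1G05340, without Col-0 replicate 2. In rdr6-15 the means of AT5G39520, AT1G05340 and AT1G09500 were 4.02, 4.43 and 2.81, against 8.02, 7.39 and 6.27 in Col-0. For 37 of the 39 probe sets both rdr6-15 arrays lay below both Col-0 arrays, which are the arrays the 39 were chosen on, so this count is not independent. In the double against rdr6-15, which uses no Col-0 array, the 39 had a median difference of 0.03. The 12 late pollen probe sets had a median difference of -2.34 in ddm1-2 and all 12 lay below 0, among them AT59 with -2.83, AT2G15880 with -2.86 and AT5G15110 with -2.72. MGH3, the 1 gene of 18 on the mature pollen list fixed beforehand that the annotation matched, differed by -0.56 (adjusted p = 0.326). The late pollen list was added after the data were seen. It was lower by camera (adjusted p = 4.12e-11), with an adjusted p = 0.206 with an estimated correlation, and 0 of its members were called over all probe sets and 10 adjusted over the list alone. Without rdr6-15 replicate 1, 9 of the 12 were called lower. Plastid-encoded genes had a median difference of 0.30 (camera adjusted p = 2.71e-05, adjusted p = 0.544 with an estimated correlation), and nuclear photosystem genes one of 0.25 (camera adjusted p = 0.0871).

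The double mutant against rdr6-15 shows the loss of DDM1 where RDR6 is already lost. Its differences share no array with those of ddm1-2 against Col-0. The spread was estimated from all 8 arrays, so the calls of the 2 comparisons are not independent. From control level in rdr6-15, AT2G13160 rose by at least 8.93 (adjusted p = 2.12e-05), AT2G12300 by 8.52, AT2G10640 by 8.40 and AT2G12240 by 8.11. AT2G04770 and AT1G33130, also annotated pseudogenes at control level, rose by at least 7.53 and 7.31, AT1G58025 by at least 7.72, and AT3G30396, from 4.13, by 7.57. The pseudogenes named here all have shared probe sets. The coding genes AT1G36240, AT2G15560 and AT5G26270 rose by at least 5.96, 5.96 and 5.51, and AT1G59930 by 4.63. AT2G23480 rose from a mean of 2.99, at control level, to 5.09 (adjusted p = 0.0074). There were 37 probe sets higher, 33 of them at control level in rdr6-15, and 0 lower, with 1102 at an unadjusted p under 0.05 in limma. Annotated pseudogenes were 29 of the 37 (Fisher's exact test, p = 6.02e-33). Of the 37, 35 were also among the 92 higher in ddm1-2, where 0.15 would be expected from independent calls. Without rdr6-15 replicate 1 there were 64 higher and 11 lower, and without rdr6-15 replicate 2, which leaves replicate 1 alone, 4927 probe sets were called.

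Across all 22746 probe sets the differences made by ddm1-2 with and without RDR6 correlated at r = 0.289 (Spearman 0.092), and within the annotated pseudogenes at r = 0.83 (Spearman 0.467). The correlation over all was 0.112 without annotated pseudogenes. Leaving out 1 array moved it to between 0.083, without rdr6-15 replicate 2, and 0.524, without rdr6-15 replicate 1. Of the 92 probe sets higher in ddm1-2, 86 were above 0 in the double against rdr6-15, with a median of 1.98. Of the 39 lower in ddm1-2, 17 were below 0 there.

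Against Col-0, the double mutant shows the loss of both. From control level in Col-0, AT2G13160, AT2G10640, AT2G12300 and AT2G12240 rose by at least 9.13, 8.73, 8.63 and 8.20, and AT2G04770, AT2G13870 and AT1G33130 by at least 7.79, 7.75 and 7.67. These pseudogenes again all have shared probe sets. AT1G58025 rose by at least 7.53 (adjusted p = 1.46e-05) and AT2G23480 by at least 2.23 (adjusted p = 0.00546), and QQS, from 4.03, by 1.82 (adjusted p = 0.0344). AT5G39520, AT1G05340 and the pyruvate orthophosphate dikinase gene PPDK fell, with differences of -3.66, -2.50 and -1.84. AT3G61930, AT1G74010, AT1G18990, AT3G26860 and AT3G49210 fell to control level, with differences of -2.18, -1.98, -1.74, -1.66 and -1.65 that are limits. Late pollen genes had a median difference of -2.64, with 12 of 12 called adjusted over the list alone and 0 over all (camera adjusted p = 8.27e-14, adjusted p = 0.151 with an estimated correlation). There were 48 probe sets higher, 36 of them annotated pseudogenes (Fisher's exact test, p = 2.17e-39), and 23 lower. Of the 48, 43 were at control level in Col-0, and of the 23, 13 were at control level in the double. Without rdr6-15 replicate 1 there were 234 higher and 650 lower, and without Col-0 replicate 2 the total fell from 71 to 22, all of them higher. No lower call was left without either Col-0 array, and 1 or 2 were left without an array of ddm1-2 or of the double.

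The double mutant against ddm1-2 asks whether transcripts released by the loss of DDM1 depend on RDR6. AT2G15140 fell by 5.23 (SE 0.46, adjusted p = 0.0381), from a mean of 8.73 in ddm1-2 to control level (3.50) in the double, with 2.77 in Col-0. Replicates 1 and 2 of the double had 4.25 and 2.75, so control level rests on their mean and replicate 1 lay above it. The size of the fall of AT2G15140, and of the others that end at control level, is a lower limit. The annotated pseudogenes AT3G32900, AT3G47260 and AT4G03790 fell with differences of -4.91, -4.66 and -4.13, and AT2G13890 and AT2G14350, to control level, with -3.49 and -3.19. AT3G30610, an annotated pseudogene with a probe set of its own, fell by 3.65 (SE 0.17, adjusted p = 0.00298), from 6.13 to 2.48, which is control level, beside 2.47 in Col-0. The coding gene AT4G29200 fell by 4.06 (adjusted p = 0.0457), from 6.55 to 2.49, at control level. Of the transposons listed by name, AtMu1 differed by -1.24 and AT2G23480 by 0.45, with 0 of the 4 called over all probe sets, 1 adjusted over the list alone, and a list median of -0.07 (camera adjusted p = 0.661). AT2G23480 was the 1 named transposon higher in the averaged ddm1-2 effect, and 0 of this planned set were called here. AT2G13160, AT2G12300 and AT1G58025 had means of 11.92, 11.39 and 10.58 in the double, beside 11.83, 11.38 and 11.04 in ddm1-2.

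There were 12 probe sets lower, 8 of them at control level in the double, and 1 higher in the double than in ddm1-2, with 616 at an unadjusted p under 0.05. The 1 higher, by 1.59, was a probe set without a listed gene. Annotated pseudogenes were 10 of the 12 (Fisher's exact test against all probe sets, p = 1.41e-12), 9 of these with shared probe sets and 1, AT3G30610, with its own. Each of the 12 had a higher mean in ddm1-2 than in Col-0. The class already made up 71 of the 92 probe sets called higher there, so this p does not show that the fall favoured the class. Outside the naming rule and chosen after their values were seen, the rest of the 12 were AT3G33066, AT1G42360 and AT3G31540, with differences of -2.70, -2.33 and -2.24, and a probe set without a listed gene, with -2.74. These calls moved with single arrays: 0 probe sets were called without ddm1-2 replicate 1, without ddm1-2 replicate 2 or without replicate 2 of the double, 1 without either Col-0 array, and 44 without either rdr6-15 array. With shared probe sets left out, 1 was called, and with dim probe sets left out, 0. With the replicate number as block, 1 was called.

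**Figure D2:**
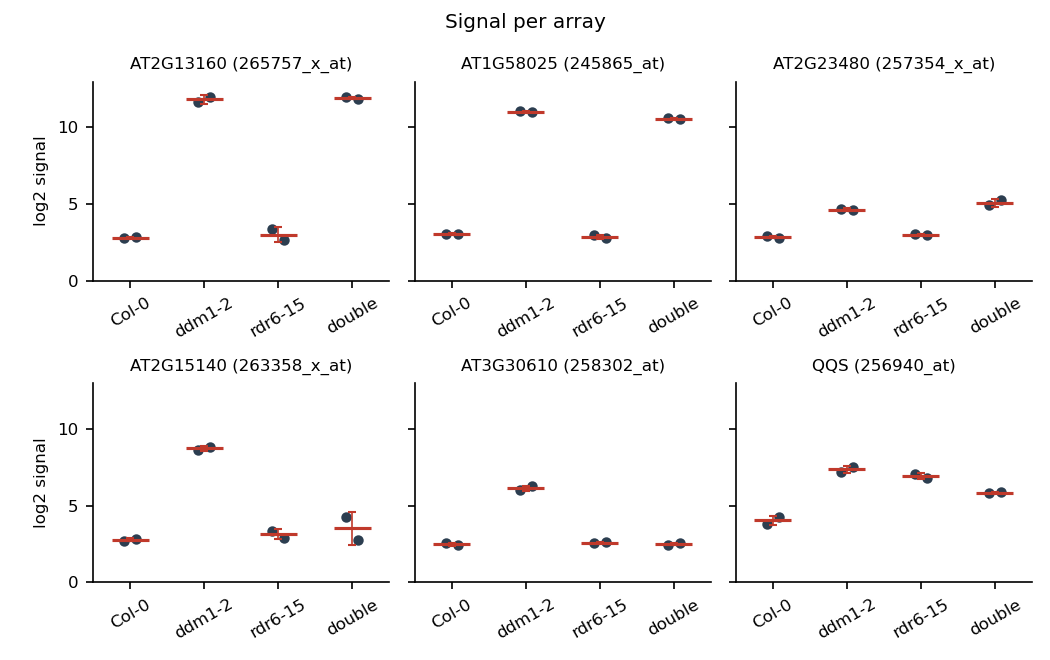
Log2 signal of 6 probe sets on each of the 8 arrays, with 2 points per genotype, the mean as a line and the standard deviation as a bar. AT2G13160 and AT1G58025 are high in ddm1-2 and in the double, AT2G15140 and AT3G30610 in ddm1-2 alone, and QQS is lowest in Col-0.

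The 84 annotated pseudogenes called higher in the ddm1-2 effect averaged over RDR6 genotypes were followed in the double against ddm1-2. The differences of this comparison are independent of that choice, but the estimate of spread is shared. Their median difference was -0.61 (quartiles -2.27 and 0.01, range -5.23 to 0.76), and 62 of 84 lay below 0. As a set they were lower by camera (adjusted p = 6.56e-38). With an estimated correlation the set did not pass once adjusted over the 5 lists added after the data were seen (unadjusted p = 0.0261, adjusted p = 0.13 with an estimated correlation), and fry gave an adjusted p = 0.0337. Of the 84, 24 were at least 2 log2 units lower and 38 stayed within 0.5. Shared probe sets were 22 of the 24 and 20 of the 38. Over the 84, shared probe sets were more frequent among those at least 2 lower than among the rest (Fisher's exact test, p = 0.00377). Since shared probe sets may count a few transcripts many times, they are not independent and this p may be too small. Per array, the 24 had medians of 8.26 and 8.64 in ddm1-2, 4.32 and 3.41 in the double, and 2.95 and 2.86 in Col-0. With shared probe sets left out the median difference was -0.16, and without ddm1-2 replicate 2 it was -0.31.

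**Figure D3:**
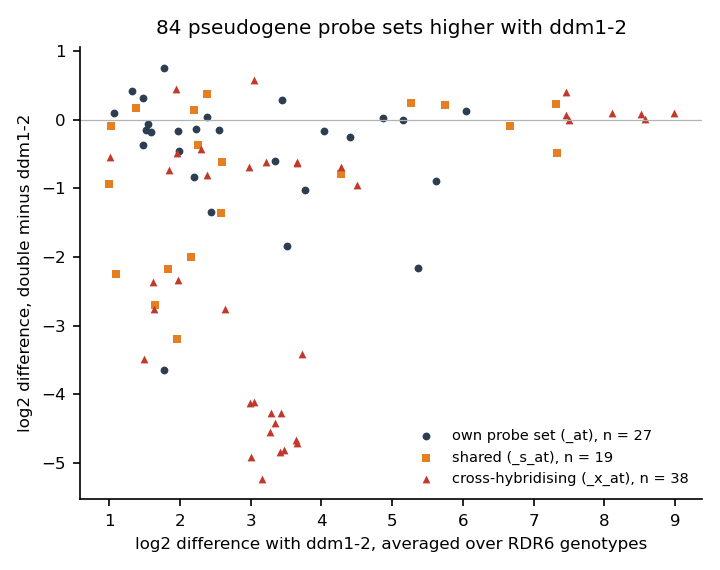
Log2 difference of the double minus ddm1-2 (vertical) against the averaged ddm1-2 difference (horizontal) for 84 annotated pseudogene probe sets, by probe set type. The lowest 12 are all of the type _x_at, and those with the largest averaged difference lie near 0.

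The comparison of rdr6-15 with Col-0 shows the loss of RDR6 where DDM1 is present. QQS rose by 2.91 (SE 0.22, adjusted p = 0.0453), from 4.03 to 6.94, and a probe set without a listed gene fell by 2.30 (adjusted p = 0.0408). These were the 2 called, with 2270 at an unadjusted p under 0.05. QQS was also called without either rdr6-15 array, but not without any 1 array of another genotype. After quantile normalization, with the replicate as block, with only the 2 genotypes fitted or with array weights, QQS was not called. AT1G05340, AT3G61930 and AT1G79520 differed by -2.96, -2.20 and -1.68 without passing (adjusted p = 0.0627, 0.0627 and 0.111). For the tasiRNA targets, which RDR6-dependent RNAs regulate, 7 of 27 listed loci were matched, and all 7 probe sets were at control level in every genotype, AT1G63400 and AT5G16640 among them. The same held for all 5 probe sets of other sources of secondary siRNAs, so that a change which stayed at that level could not be seen in either list. Their camera adjusted p-values were 0.899 and 0.635. Annotated pseudogenes had 0 called. Of their 989 probe sets, 782 were at control level in every genotype, so the same limit holds for most of the class. Late pollen genes had a median difference of -1.71 (camera adjusted p = 6.53e-09, adjusted p = 0.339 with an estimated correlation). Plastid-encoded genes had one of 0.94 (camera adjusted p = 1.2e-16, adjusted p = 0.339 with an estimated correlation), and nuclear photosystem genes one of 0.69 (camera adjusted p = 0.00241, adjusted p = 0.339 with an estimated correlation).

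These list values rest on unlike replicates. In rdr6-15 replicate 1 the late pollen median was 2.93 and the plastid-encoded median 7.43, against 5.14 and 5.63 in replicate 2. On replicate 1, 66 probe sets lay more than 3 log2 units above every other array and 112 below, while each of the other 7 arrays had 0 of either kind. The aminotransferase gene BCAT4 had 8.15 on it and at most 3.24 elsewhere, and the thionin gene THI2.1 had 2.70 on it and at least 9.07 elsewhere. Without replicate 1, 6 probe sets were higher and 23 lower in rdr6-15 than in Col-0, and without replicate 2, 5414 were called.

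**Figure D4:**
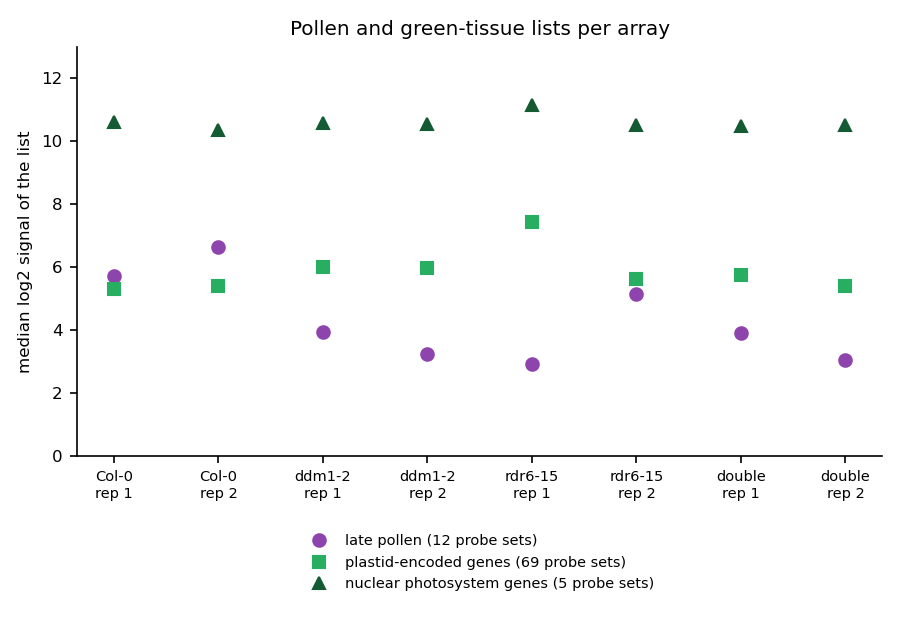
Median log2 signal of 3 lists on each array, by genotype and replicate. Late pollen genes are highest in both Col-0 arrays, and rdr6-15 replicate 1 has the highest plastid-encoded median and the lowest late pollen median.

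The interaction asks whether the loss of DDM1 acts differently with and without RDR6. QQS had an interaction of -4.43 (SE 0.31, adjusted p = 0.0277), with means of 4.03 in Col-0, 7.37 in ddm1-2, 6.94 in rdr6-15 and 5.85 in the double. AT3G30610 had one of -3.76 (SE 0.23, adjusted p = 0.0249). AT3G33066, AT2G13890 and AT1G05340 had values of -2.98, -3.56 and 3.71 that did not pass (adjusted p = 0.0989, 0.106 and 0.106). AT3G30610, AT3G33066 and AT2G13890 were above control level in ddm1-2 alone, so the sizes of their interactions are not determined. The 2 lower were all that passed, with 1430 at an unadjusted p under 0.05 in limma. Without rdr6-15 replicate 1 QQS and AT3G30610 passed, both with an adjusted p of 0.00241, and without any 1 array of another genotype neither passed.

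Averaged over RDR6 genotypes, ddm1-2 gave 104 probe sets higher, 84 of them annotated pseudogenes, and 12 lower. Without rdr6-15 replicate 1 these were 231 and 397, without rdr6-15 replicate 2 they were 2371 and 1768, and without any 1 array of Col-0 or ddm1-2 they were 51 to 62 and 0. Averaged over DDM1 genotypes, rdr6-15 gave 0 higher and 1 lower, AT3G30610 with an averaged difference of -1.77 (adjusted p = 0.0375), with 1362 at an unadjusted p under 0.05 in limma. This gene did not fall with DDM1 present (2.47 in Col-0 and 2.58 in rdr6-15, both at control level), so the average comes from its fall in the double against ddm1-2. The differences made by rdr6-15 with and without DDM1 correlated at r = 0.026 across probe sets (Spearman -0.005). Among the lists fixed beforehand, silencing machinery, meiosis genes, tasiRNA targets and other sources of secondary siRNAs had camera adjusted p-values of 0.147 or more in every comparison of genotypes. The 4 probe sets of meiosis genes and 3 of the 5 of silencing machinery were at control level in every genotype. AGO7 differed by 0.59 in ddm1-2 and 0.33 in rdr6-15, and SPO11-2 by -0.28 and -0.17, none passing. No probe set was listed for DDM1, RDR6 or the tasiRNA loci, so their levels were not analysed here.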

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

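All tests of the 3 patterns below were chosen after the results were seen; the counts over splits of the arrays were planned before.

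QQS was picked out because ddm1-2 acted differently on it with and without RDR6, by a test of the interaction (-4.43, adjusted p = 0.0277). AT3G30610 was picked out by the same test (-3.76, adjusted p = 0.0249), with a size not determined, since it was above control level in ddm1-2 alone. A pair of control probe sets, outside the comparisons, stood above the highest Col-0 array in rdr6-15 replicate 1. These were the 5S ribosomal RNA control, with 4.79 against 2.94, and the control U12639, with 5.51 against 2.48. Outside that rule, the control BioB-3 had 10.26 and 9.71 on the Col-0 arrays, at most 9.12 elsewhere and 7.20 on ddm1-2 replicate 2. BioC-3 had 10.65 and 10.17 in Col-0 and at most 9.58 elsewhere, but the r2 control cre-3 was highest on ddm1-2 replicate 1 (14.17). Whether this difference of the Col-0 arrays bears on the lower calls was not tested.

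Splitting the 8 arrays 4 against 4 gave 35 splits. The split by DDM1 genotype called 78 probe sets, and the highest of the other splits called 0. So 1 of 35 gave as many, the smallest share that 35 splits can give, which does not exclude chance. All other splits mix the DDM1 genotypes, so the DDM1 differences widen their spread and make low counts likely beforehand. The split by RDR6 genotype called 0, against a highest other of 78, for the split by DDM1. With a count of 0 all 35 splits give as many whatever the data, so this count does not exclude chance and shows nothing more. The splits have no term for the other mutation; with a mean per genotype 1 probe set, AT3G30610, was called.

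The first pattern is that rdr6-15 replicate 1 stands apart from the other arrays. Degraded RNA alone would add no transcripts, though scaling between arrays can raise the relative signal of those that remain. On this array 66 probe sets lay more than 3 log2 units above every other array. That argues against degraded RNA alone but does not exclude it. A wrong label on RNA of ddm1-2 or the double is argued against too: over 130 pseudogene probe sets called higher with ddm1-2 without that array, it lay 0.312 above the Col-0 mean, where ddm1-2 lay 2.40 above. Green or vegetative tissue in that sample may be a source, since nuclear photosystem genes were higher by a median of 0.792 than in replicate 2. By the r2 control probe sets, the 3' minus 5' difference there was 2.98 for actin (at most 2.17 elsewhere) and 1.05 for ubiquitin (at most 0.527). For GAPDH it was -0.507, inside the -1.08 to -0.303 of the other arrays. By the Athal probe sets of these controls it was the largest of all arrays for GAPDH (7.92 at 3', 7.15 at 5') and ubiquitin (10.78 and 8.32). For actin it was the smallest there (8.38 and 4.29). So the controls differ and lower RNA quality stays open.

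The second pattern is that late pollen genes were lower in ddm1-2 and the double than in Col-0. After quantile normalization the median difference was -2.39. The deposited arrays already had like quartiles, so this step could hardly move the list and does not decide on scaling. Array medians lay between 3.73 and 3.82, too close for an overall shift of that size. The bioB, bioC, bioD and cre controls, except r2 cre-3, were also highest on the Col-0 arrays, and a technical difference of those arrays was not tested. Flower stage or anther share of the tissue may differ between samples and cannot be told apart from an effect of genotype: the list median differed by 0.929 between the Col-0 arrays, against -2.61 between genotypes, with 2 arrays each. Over all genotypes the widest gap was 2.21, in rdr6-15, which would favour tissue composition; the test was narrowed to the other genotypes after that value was seen, because that gap belongs to the first pattern. An effect of the mutations on pollen stays open as well, as untested.

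The third pattern is that part of the pseudogene probe sets that rose with ddm1-2 is lower in the double. Scaling is argued against, since 23 probe sets of like brightness in ddm1-2 stayed within 0.5 log2 units. Probe sets shared by related copies may count a few transcripts many times, and 2 of the 24 at least 2 units lower had probe sets of their own, too few to decide how many separate loci fell. That loss of RDR6 lowers these transcripts stays open as the explanation the design names. The 12 lowest were all of the type _x_at, with replicate 1 of the double above replicate 2 in 12 of 12.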

How the results depend on the processing

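Array weights and all alternatives for the annotated pseudogenes, the added lists and the correlations by array were chosen after seeing the data. The replicate numbers do not pair the arrays throughout: deviations from the genotype means correlated at -0.06 to 0.422, against a limit of 0.1. Over it were ddm1-2 with the double (0.422) and Col-0 with rdr6-15 (0.155). The replicate block is therefore an alternative only, but a shared replicate effect in the double against ddm1-2 stays open. Below, comparisons are in the order ddm1-2, rdr6-15 and double against Col-0, double against ddm1-2, double against rdr6-15, interaction, and averaged ddm1-2 and rdr6-15 effects. Each cause was not tested unless arrays or probe sets were left out.

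Main totals of 131, 2, 71, 13, 37, 2, 116 and 1 called probe sets changed by more than 1.5 times as follows. With the replicate as block, rdr6-15 gave 0, the double 39, double against ddm1-2 1, the interaction 0 and averaged rdr6-15 0; higher pseudogenes in the double were 23 and lower ones against ddm1-2 1. Fitting only the genotypes compared gave 1313, 0, 705, 29 and 17, with pseudogenes 144, 71, 23 lower and 12. Without shared probe sets totals were 40 for ddm1-2, 22, 1, 11 and 38 for the averaged effect, with pseudogenes 13, 8, 1 lower and 6. Array weights gave 643, 0, 556, 38 and, for the interaction, 5, with pseudogenes 122, 69 and 31 lower. Without dim probe sets double against ddm1-2, the interaction and averaged rdr6-15 gave 0, with 0 pseudogenes lower. Quantile normalization gave 1 for rdr6-15 and 4 for the interaction. Trend and robust gave 5 for rdr6-15, 24 for double against ddm1-2, 4 for the interaction and 21 pseudogenes lower. Adjusted p under 0.01 left 64, 0, 29, 1, 0 for the interaction, 61 and 0, with 21 pseudogenes higher in the double and 1 lower.

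Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 31 to 1084, 0 to 5414, 22 to 884, 0 to 44, 26 to 4927, 0 to 3810, 51 to 4139 and 0 to 3791. The highest values came without an rdr6-15 array; for comparisons that use rdr6-15, without its replicate 2, so that replicate 1 stood alone. Pseudogenes ranged over 24 to 135, 17 to 73 and 20 to 64 higher, and 0 to 32 lower. Named transposons called, 1 each in ddm1-2, the double, double against rdr6-15 and averaged, ranged over 0 to 2, 0 to 1, 0 to 1 and 1 to 2. They were 0 without shared probe sets, 2 in ddm1-2 with array weights or the 2 genotypes alone, and 0 for double against rdr6-15 with those alone.

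The correlation of ddm1-2 effects, 0.289, was 0.112 without pseudogenes and 0.083 to 0.524 by array left out, and that of rdr6-15 effects, 0.026, was -0.09 to 0.137. Ranges of adjusted p next are by array left out only. Annotated pseudogenes in rdr6-15 against Col-0 (0.544) reversed without rdr6-15 replicate 1 (0.000565, range to 0.554) and passed in the first direction without replicate 2 (0.00327). Without rdr6-15 replicate 2, late pollen (0.346, range 2.55e-11 to 0.795) and annotated pseudogenes (0.608, range 5.17e-18 to 0.608) reversed in double against rdr6-15. For called named genes, 866 of 1074 alternatives kept the call, 208 lost it and 0 reversed; for called lists, 192 of 233 kept it, 39 lost it and 2 reversed. With an estimated correlation 3 of 18 list calls held. All 3 were the 84 pseudogene probe sets called higher in the averaged ddm1-2 effect, in ddm1-2 and the double against Col-0 and in the double against rdr6-15. That list was chosen for being higher on these same arrays, so the 3 calls, which are also among the 192, show nothing more. Scalings shifted the median of all probe sets by at most 0.053. A test of pericentromeric position was not run, since no build is named. The number of arrays and their pooled spread together limit what can be seen: of 50 simulated changes of 1 log2 unit, 6 were recovered.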

Other observations

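Of the 39 probe sets lower in ddm1-2 than in Col-0, 37 were below both Col-0 arrays in both rdr6-15 arrays, with a median difference of -1.45 between rdr6-15 and Col-0. Both comparisons share the Col-0 arrays, on which the bioB, bioC, bioD and cre controls, except r2 cre-3, were also highest. Between the double and rdr6-15, which share none of them, the same 39 had a median difference of 0.03.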
